A study of Homo sapiens with 8 samples.

How the data were processed

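HaCaT cells, an established line of human keratinocytes, had been transfected with a small interfering RNA (siRNA) against KEAP1 or with a scrambled siRNA. Labelled RNA of each siRNA sample had been hybridised together with a common reference, RNA of cells that received the transfection reagent without siRNA, on Agilent whole-genome arrays with 2 colours. Per the labels there were 8 arrays, 2 biological replicates per group, and 2 arrays per biological replicate with the dyes Cy3 and Cy5 exchanged.

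Per the file headers, the images had been read with Agilent Feature Extraction 9.5.3.1, and the mean signal and the local background of each spot are given as intensity, the brightness on a linear scale without correction. The deposited processed signals are also intensity, after background subtraction with spatial detrending and dye normalization by Feature Extraction. The deposited log ratios are log10 of processed Cy5 over processed Cy3. They equalled that ratio within 0.001 for 87.6% to 95.8% of the spots of an array, and all other spots were set to 0. Each array carried 43931 spots, of which 2256 were control spots.

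The mean signals were corrected for background with normexp (offset 50) on all spots and normalised within each array by loess with control spots at weight 0. This was done with limma 3.58.1 in R 4.3.3, with the package data.table, version 1.17.8, to read the files. Each array's log2 ratio was turned to siRNA sample over mock reference by the labelled dyes, and the 2 arrays of a biological replicate were averaged, so that a replicate counted once and the dye effect cancelled. Of 41000 probes that are not controls, 23146 were named through their accession, 2436 through a current symbol and 1114 through a synonym. The other 14304 kept the name in the file. A probe was kept when it was well above background in the siRNA channel on at least 4 of the 8 arrays. This held for 34504 probes, and 253 probes were left out for an outlier spot. The siRNA channel was taken from the labelled dyes, also when turned. The same holds for each statement below on the background or saturation of a single gene. The brightest kept probe stood for each gene, which gave 26288 genes or unmatched names, 15973 of them with an official symbol. Probe positions are those of the files, on hg17.

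The groups were compared with limma's lmFit and eBayes, as 2 biological replicates against 2, with 1 estimate of the spread shared by both groups. Each group was also compared with a ratio of 0 to the mock reference, which stands as 1 RNA whose own spread is left out. The tests were 2-sided with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. An exact permutation test of 2 against 2 cannot go below p = 0.333, so no single gene was tested that way. The 30 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and also with an estimated correlation and with fry, whose directional test asks whether a list's genes move one way on balance and whose mixed test asks whether they change in either direction. With an estimated correlation camera rests on the 2 residual degrees of freedom of the fit, the data left to set the spread. A list can hardly pass there after adjustment, so failing it says little about the list. A list whose estimated correlation lies well above 0.01 may in turn pass too easily at the preset correlation. The lists, the comparisons, the main settings and the rule for naming genes were fixed before the data were examined.

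That rule named KEAP1 and NFE2L2, then the 14 largest increases and the 10 largest decreases between the siRNAs among genes past the threshold whose replicates did not overlap. Where none passed, it named the 10 genes of lowest p in each direction. It added up to 4 members of smallest p from each list, and the 5 largest changes each way against the mock reference. For near-identical families (AKR1C, GST, UGT1A, KRT6, HSPA1, metallothioneins) a probe may not tell the members apart.

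The ratios of the 2 KEAP1 replicates ran in opposite directions under the labelled dyes. Every comparison is therefore given as labelled and also with the sign of both arrays of the replicate labelled KEAP1 biological replicate 1 turned, called "turned" throughout. This second set of fits was chosen after seeing the data, and the same alternatives were run on it. Also run were other background corrections and normalizations, other filters on dim probes, the mean of a gene's probes, all 8 arrays with the biological replicate as a random block, arrays of 1 dye orientation, another variance model, the slide run and the replicate number as blocks, other thresholds, and leaving out each biological replicate. Turning either KEAP1 replicate, leaving out KEAP1 array 2 or array 3, crossing the replicate numbers in the block, and choosing genes in 1 slide run to look at them in the other were added after seeing the data.

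The route was tested on simulated data with 50 genes at each of 4 sizes of change. Simulated genes varied independently with the spread of the turned fit, the dye bias was equal on all arrays, and slide runs did not differ. The shares below hold for that setting, and real arrays may do worse. At 1.5-fold 78% of the changed genes were called, and at 2-fold, 4-fold and 8-fold 100%, with 11 unchanged genes among 200 calls and 0 calls of the wrong sign. The median log2 change recovered was 90.4% of the true one at 2-fold. When 1 simulated KEAP1 replicate was mirrored, 0 genes were called by limma (1089 at an unadjusted p under 0.05). Figures were drawn with matplotlib 3.10.9. Arrays give no count of molecules, so the number of arrays and the signal over background limit the precision.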

Results

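Gene expression was measured in HaCaT cells, an immortalised human keratinocyte line, after transfection with an siRNA against KEAP1 or with a scrambled siRNA that has no intended target. KEAP1 is the adaptor protein through which cells degrade the transcription factor NRF2 (gene NFE2L2), and the series title names the antioxidant genes under NRF2. Every array set 1 siRNA sample against RNA of mock-transfected cells. There were 2 KEAP1 siRNA replicates and 2 scrambled siRNA replicates, each on 2 arrays with the dyes exchanged. The labels call the replicates biological and do not say whether they were separate cultures, so p-values measure the spread between these samples. The median spot signal was 215 to 309 in Cy3 and 227 to 343 in Cy5, except for 703 in Cy5 on KEAP1 array 3. Cy3 signals were well above background at 60.5% to 84.2% of the spots and Cy5 signals at 80.1% to 99.3%. Ratios below are log2 of siRNA sample over mock reference, and differences between the siRNAs are log2 KEAP1 siRNA minus scrambled siRNA, with the standard error of the limma fit and n = 2 biological replicates per group.

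The KEAP1 probe (hg17 chromosome 19, 10458262 to 10458321) gave opposite ratios in the 2 KEAP1 siRNA replicates. Under the labelled dyes KEAP1 mRNA was above mock on both arrays of the replicate labelled 1, by 1.79 and 1.08, and below mock on both arrays of the replicate labelled 2, at -1.53 and -1.13. AKR1C1, an aldo-keto reductase known as an NRF2 target, was at -3.04 in the replicate labelled 1 and at 3.00 in the replicate labelled 2. All 15 genes beyond 1 log2 unit in both replicates had opposite signs. Across all genes, which are not independent replicates, the ratios of the 2 KEAP1 replicates correlated at r = -0.463, and those of the 2 scrambled replicates at r = 0.583. The labels therefore do not settle the direction of the KEAP1 siRNA ratios. The direction with the replicate labelled 1 turned is the likely one, on the basis that KEAP1 mRNA, the target of the siRNA, is then below mock in both replicates. All directions given as turned rest on that reading.

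**Figure D1:**
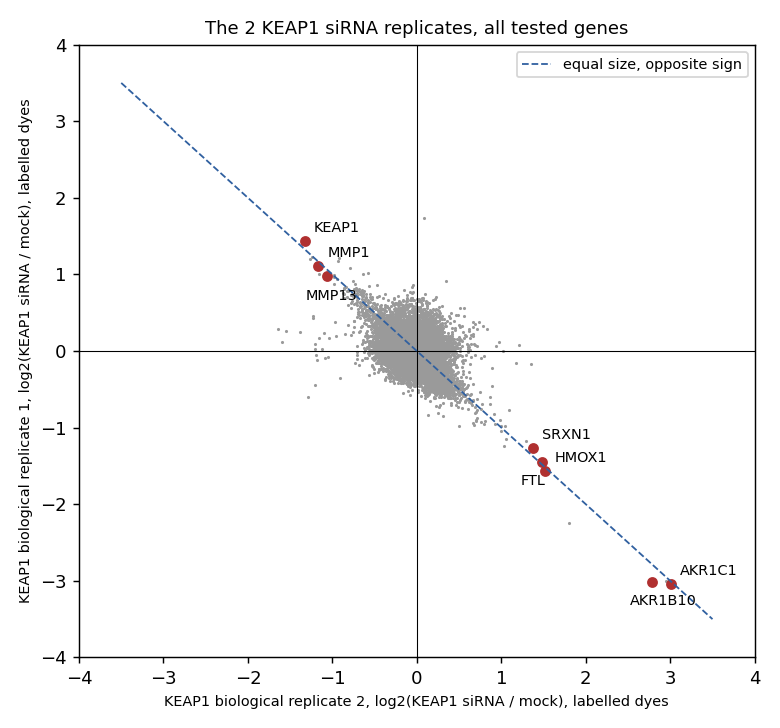
Log2 ratio of KEAP1 siRNA over mock in KEAP1 biological replicate 2 (horizontal axis) and in KEAP1 biological replicate 1 (vertical axis), 1 point per tested gene, labelled dyes. The named genes lie along the line of equal size and opposite sign, from KEAP1 at the upper left (-1.33 and 1.43) to AKR1C1 at the lower right (3.00 and -3.04).

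**Figure D2:**
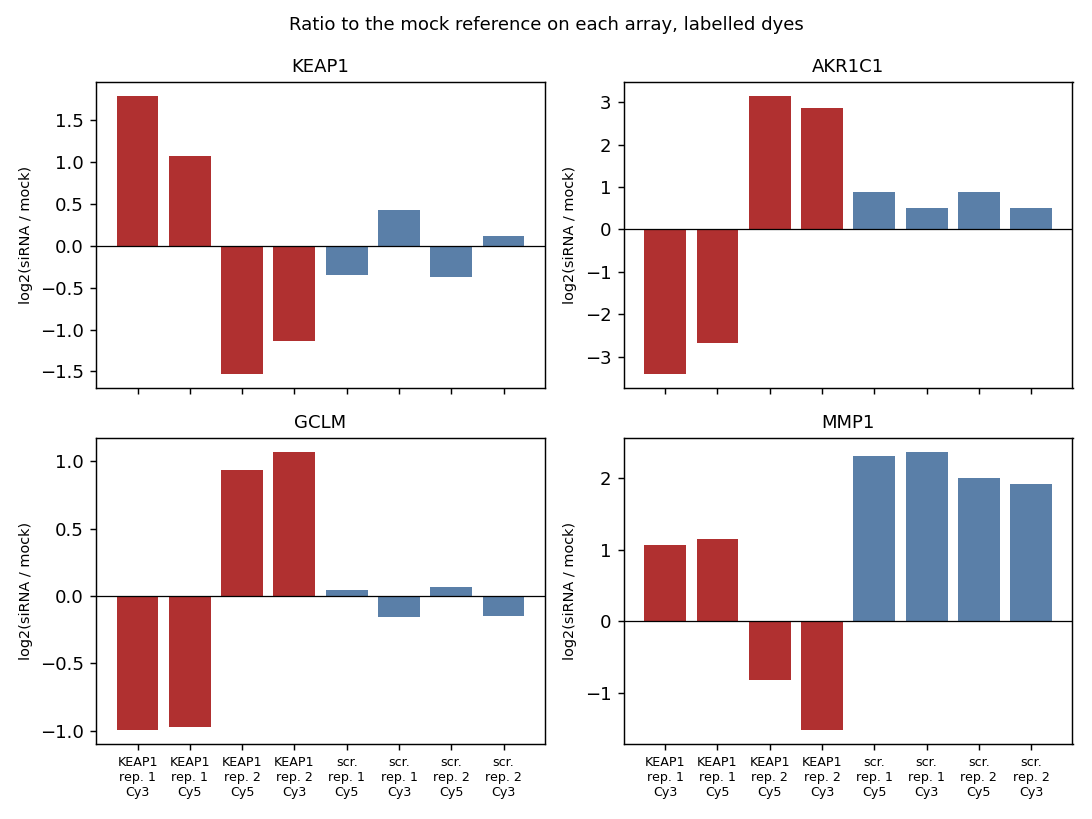
Log2 ratio of siRNA sample over mock on each of the 8 arrays for KEAP1, AKR1C1, GCLM and MMP1, labelled dyes; each bar is 1 array, with its replicate and the dye of the siRNA sample below it. In all 4 genes both arrays of KEAP1 replicate 1 have the sign opposite to both arrays of KEAP1 replicate 2.

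The comparison of KEAP1 siRNA with scrambled siRNA asks which genes lowering KEAP1 changes beyond the effect of transfecting an siRNA. As labelled, 0 of 26288 genes passed the threshold in limma, 1911 had an unadjusted p under 0.05, and the lowest adjusted p was 0.534. The genes nearest the threshold had near-equal values in both KEAP1 replicates and missed it at an adjusted p of 0.534. Higher values were found for TMEM109, a membrane protein (1.23 ± 0.11), CNIH4 (1.10 ± 0.18), SIVA1, an apoptosis-linked gene (1.02 ± 0.11), EIF4G2 (0.94 ± 0.12), NIF3L1 (0.90 ± 0.13), GPX4 (0.83 ± 0.13), SUMO2 (0.77 ± 0.12), UQCC2 (0.74 ± 0.12) and MBNL1 (0.70 ± 0.11). Lower values were found for MMP12, a macrophage elastase (-1.48 ± 0.17), PLAT, the tissue plasminogen activator (-1.19 ± 0.14), VAV3 (-1.18 ± 0.12), INHBA (-1.02 ± 0.14), MARCKS (-1.01 ± 0.13), ACTG1 (-0.93 ± 0.11, saturated on 2 of the 4 arrays of each group), FHOD3 (-0.89 ± 0.12), ACOT11 (-0.88 ± 0.11), B3GNT5 (-0.87 ± 0.11) and KDM1A (-0.83 ± 0.11). Genes whose ratios had opposite signs in the 2 KEAP1 replicates averaged near 0 with wide errors, such as KEAP1 (0.10 ± 0.81), GCLM (0.06 ± 0.59) and NQO1 (0.02 ± 0.56). NFE2L2 was at -0.54 ± 0.12 and missed the threshold (adjusted p = 0.557).

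Of the 30 lists as labelled, 5 passed camera with the preset correlation, and 0 of their members passed the threshold for single genes, nor did any when adjusted over the list alone. Lower in KEAP1 siRNA were the basal keratinocyte genes (median -0.29, adjusted p = 0.000657), cholesterol and fatty acid synthesis (median -0.17, adjusted p = 0.0106), hypoxia and glycolysis (median -0.17, adjusted p = 0.0248) and metallothioneins (median -0.23, adjusted p = 0.045). Cell cycle genes were higher (median 0.22, adjusted p = 0.000657). All 5 lists also passed in scrambled siRNA against mock, in the opposite direction. The opposed KEAP1 replicates averaged out: the mean ratio of basal keratinocyte genes to mock was -0.01 in KEAP1 siRNA and 0.38 in scrambled siRNA. For cholesterol genes these means were -0.04 and 0.13. The 5 differences thus lay mostly in the scrambled ratio and do not by themselves show a change in KEAP1 siRNA cells. With an estimated correlation none of the 5 passed (adjusted p = 0.788 to 0.885). With the replicate number as a block 5 lists and 0 genes passed, with 2279 genes at an unadjusted p under 0.05. Leaving out the replicate labelled KEAP1 1 gave 346 genes and leaving out the replicate labelled KEAP1 2 gave 1889, with KEAP1 mRNA at -1.29 and 1.48 respectively.

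With the replicate labelled KEAP1 1 turned, KEAP1 siRNA cells held less KEAP1 mRNA than scrambled siRNA cells, more mRNA of some aldo-keto reductase, glutathione, heme and NADPH genes, such as AKR1C3, GCLC, HMOX1 and PGD, and less of others, such as MMP1, KRT1 and TP63. The lists behind these genes moved only in part. None passed with an estimated correlation, a test that rests on 2 residual degrees of freedom and can hardly pass a list. By fry's directional test 8 of the 30 lists passed. They were glutathione (adjusted p = 0.00533), aldo-keto reductases (0.0203), iron and heme (0.0202), thioredoxin (0.0318), NADPH supply (0.03375), proteasome (0.0406), basal (0.00533) and differentiating keratinocyte genes (0.0169). Quinone and drug metabolism did not pass it (adjusted p = 0.0856). KEAP1 was at a difference of -1.34 ± 0.10, or 0.396 of the scrambled level, which is no separate evidence because the turn was chosen on its direction (0.10 ± 0.81 as labelled). AKR1C3 and AKR1C1 were 5.19-fold and 5.00-fold higher, and MMP1, the interstitial collagenase, was 9.78-fold higher in scrambled siRNA cells. In total 471 genes passed, 174 higher and 297 lower in KEAP1 siRNA, against 69 higher and 379 lower with median centring, 4 genes without scrambled replicate 1 and 25 without scrambled replicate 2. NFE2L2 itself did not pass (-0.37 ± 0.11, adjusted p = 0.162). The mock reference shows in which group these genes departed from it: of the 174 higher genes, 61 had the KEAP1 siRNA ratio further from 0 and 113 the scrambled siRNA ratio, and of the 297 lower genes 124 and 173.

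**Figure D3:**
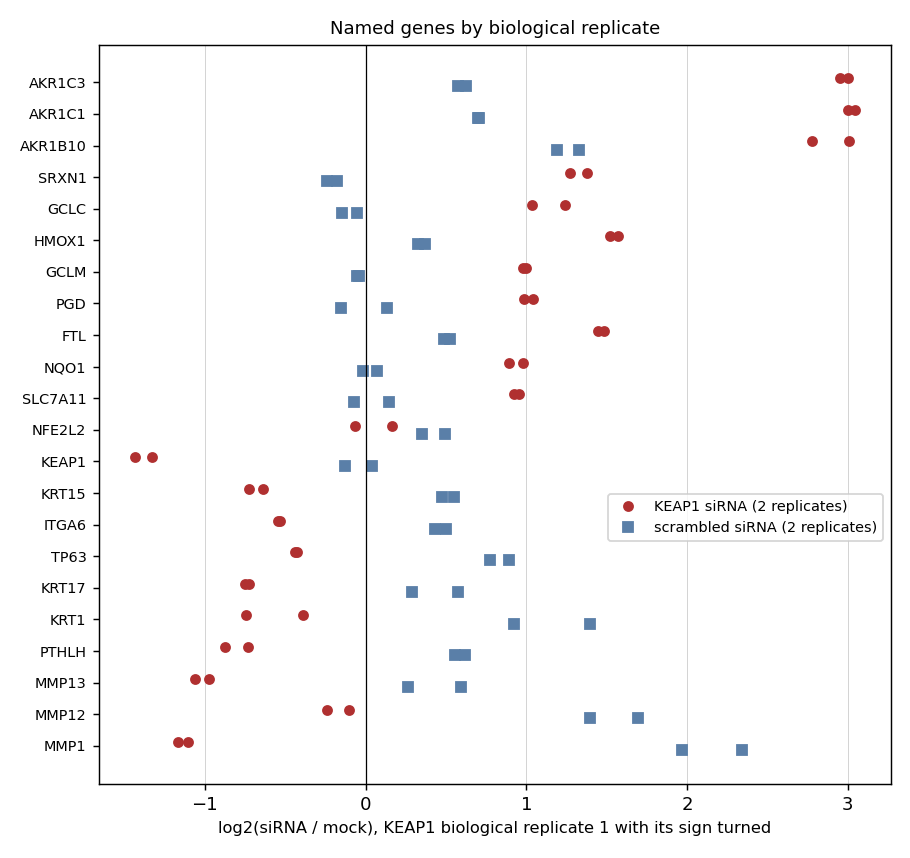
Log2 ratio of siRNA sample over mock (horizontal axis) for named genes (vertical axis), with KEAP1 biological replicate 1 turned; circles are the 2 KEAP1 siRNA replicates and squares the 2 scrambled siRNA replicates. AKR1C3 lies at a mean of 2.98 in KEAP1 siRNA and 0.60 in scrambled siRNA, and MMP1 at -1.14 and 2.15.

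Aldo-keto reductases, which reduce carbonyl compounds, held the largest increases when turned. Of 10 measured, 4 rose and 0 fell, namely AKR1C3 (2.38 ± 0.09, adjusted p = 0.000359), AKR1C1 (2.32 ± 0.08, adjusted p = 0.000359), AKR1B10 (1.64 ± 0.11) and AKR1B1 (0.92 ± 0.10). The list passed camera (adjusted p = 9.96e-06) and fry's directional test (adjusted p = 0.0203), and not camera with an estimated correlation (adjusted p = 0.356). Adjusted over the list alone, 4 rose and 1 fell. The probes of AKR1C1 and AKR1C3 may cross-hybridise within the family.

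Of 18 genes of glutathione synthesis and reduction, 5 rose and 0 fell when turned, and the same numbers held when adjusted over the list alone. They included GCLC (1.24 ± 0.10) and GCLM (1.04 ± 0.08), the 2 subunits of the enzyme that starts glutathione synthesis, SLC7A11, a cystine importer (0.90 ± 0.10), and GPX4, which reduces lipid peroxides (0.77 ± 0.10). GPX4 was at -0.09 against mock in KEAP1 siRNA and at -0.86 in scrambled siRNA. The list passed camera (adjusted p = 0.00103) and fry's directional test (adjusted p = 0.00533), and not camera with an estimated correlation (adjusted p = 0.354). Its median of 0.09 was -0.05 when arrays were centred on the median in place of loess.

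Of 19 genes of the thioredoxin and peroxiredoxin system 3 rose and 0 fell when turned, and 6 rose and 2 fell when adjusted over the list alone. They were SRXN1, which repairs oxidised peroxiredoxins (1.53 ± 0.09, adjusted p = 0.00516), TXN (0.67 ± 0.12) and PRDX1 (0.50 ± 0.09). By the labelled dyes TXN was saturated on 2 of the 4 KEAP1 arrays. TXNRD1 missed the threshold (0.52 ± 0.10, adjusted p = 0.0583). The list's median was 0.11 by loess and -0.02 by median centring (adjusted p = 0.00809 by camera, adjusted p = 0.354 with an estimated correlation). Of 23 genes of quinone, carbonyl and drug metabolism 4 rose and 0 fell, and 9 rose and 2 fell when adjusted over the list alone. They were NQO1, the quinone reductase (0.91 ± 0.09, adjusted p = 0.0141), CYP4F11 (0.90 ± 0.12), UGT1A6 (0.72 ± 0.09) and PTGR1 (0.54 ± 0.09), with an adjusted p = 0.00103 for the list and an adjusted p = 0.354 with an estimated correlation.

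Of 14 iron and heme genes 3 rose and 0 fell when turned, and as many when adjusted over the list alone. They were HMOX1, which breaks down heme (1.20 ± 0.09, adjusted p = 0.00661), FTL, a ferritin chain (0.96 ± 0.08), and FECH, which inserts iron into protoporphyrin to form heme (0.71 ± 0.09). The median of this list was 0.07 by loess and -0.05 by median centring (adjusted p = 0.0247, adjusted p = 0.354 with an estimated correlation). Of 13 genes of the pentose phosphate path and NADPH supply 3 rose and 0 fell, and 5 rose and 0 fell when adjusted over the list alone. They were PGD (1.02 ± 0.12), ME1 (0.62 ± 0.10) and TKT (0.50 ± 0.09), with a list median of 0.06 by loess and -0.05 by median centring (adjusted p = 0.0028, adjusted p = 0.354 with an estimated correlation). Among 19 regulators and partners of KEAP1 and NRF2, MAFG, a small Maf protein that pairs with NRF2, rose (0.52 ± 0.09) and KEAP1 fell. That list did not pass (adjusted p = 0.458). Among 18 other genes reported to respond to NRF2, FECH and LRP8 (0.62 ± 0.09) rose and RXRA fell (-0.58 ± 0.09). A dimmer RXRA probe gave -0.04. The list did not pass camera (adjusted p = 0.0756). Of 32 proteasome subunits none passed, 29 had positive values, and the median was 0.14 by loess and -0.01 by median centring (adjusted p = 2.78e-05, adjusted p = 0.354 with an estimated correlation). No glutathione S-transferase (19 measured, adjusted p = 0.597) and no ABC drug efflux transporter (9 measured, adjusted p = 0.405) passed. The nearest were GSTM3 (0.40 ± 0.08, adjusted p = 0.0748) and ABCC3 (0.57 ± 0.10, adjusted p = 0.0542).

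Part of the keratinocyte genes were lower in KEAP1 siRNA than in scrambled siRNA when turned. Of 14 basal keratinocyte genes 6 fell and 0 rose, and 13 fell when adjusted over the list alone. Among them were TP63, the transcription factor of the basal layer (-1.27 ± 0.09, adjusted p = 0.00661), KRT15 (-1.19 ± 0.09), the integrin ITGA6 and KRT14 (-0.99 ± 0.11). By the labelled dyes KRT15 was saturated on 2 of the 4 arrays of each group. The list median was -0.54 (adjusted p = 1.29e-14, adjusted p = 0.354 with an estimated correlation). Its estimated correlation, -0.065, lay below the preset 0.01, so the higher p came from the 2 degrees of freedom and not from correlation between its genes. This does not hold for every list. The estimate was also below 0.01 for glutathione genes (-0.042). It was 0.568 for wound keratins and alarmins, 0.399 for aldo-keto reductases and 0.257 for metallothioneins. For these 3 lists correlation also raised the p, and the p at the preset correlation may be too small. TP63 was at -0.43 against mock in KEAP1 siRNA and at 0.84 in scrambled siRNA, so the larger departure from mock was in the scrambled group. Of 21 genes of differentiating keratinocytes 2 fell and 0 rose, KRT1 (-1.73 ± 0.18) and the cross-linking enzyme TGM1 (-0.72 ± 0.11), with 3 when adjusted over the list alone (adjusted p = 0.0119, adjusted p = 0.354 with an estimated correlation). Of 13 wound keratins and alarmins 3 fell and 0 rose, KRT6C (-1.23 ± 0.16), KRT17 (-1.17 ± 0.11) and KRT16 (-1.07 ± 0.11), with 7 when adjusted over the list alone (adjusted p = 1.91e-06, adjusted p = 0.375 with an estimated correlation).

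Among genes with an official symbol, the largest decreases when turned were those of MMP1, KRT1, MMP12 and MMP13. MMP1 fell by 3.29 ± 0.13 (adjusted p = 0.000549), MMP12 by 1.72 ± 0.12 and the collagenase MMP13 by 1.45 ± 0.12. These 3 encode matrix metalloproteinases, secreted enzymes that cut matrix proteins, for which no list was tested. MMP1 was at -1.17 and -1.11 against mock in the KEAP1 siRNA replicates and at 2.34 and 1.97 in the scrambled siRNA replicates. MMP12 was at -0.17 and 1.55. By the labelled dyes, which were not turned for this count, its KEAP1 siRNA signal was well above background on 3 of 4 arrays. Also among the 10 largest decreases were PTHLH, the parathyroid hormone-related protein (-1.39 ± 0.09), PLEKHA1 (-1.37 ± 0.09), KRT13 (-1.34 ± 0.18) and the carbonic anhydrase CA2 (-1.28 ± 0.10). Among the 14 largest increases TMEM109 (1.31 ± 0.09), LRRC20 (1.10 ± 0.09), SIVA1 (1.06 ± 0.08), ALDH18A1 (1.04 ± 0.10) and EXOSC8 (1.02 ± 0.09) lay further from mock in scrambled siRNA, where they were at -1.24, -0.70, -1.03, -0.66 and -0.84. Dimmer probes of TMEM109, LRRC20 and TP63 gave differences of 0.22, 0.15 and -0.25.

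None of 24 proliferation genes passed between the siRNAs when turned, and 22 had positive values. Adjusted over the list alone, 13 rose and 0 fell, with PCNA, the DNA polymerase clamp, at 0.52 ± 0.09 (adjusted p = 0.0506) and E2F1 at 0.50 ± 0.10 (adjusted p = 0.0654). The list median was 0.29 (adjusted p = 1.96e-09, adjusted p = 0.354 with an estimated correlation). Of 16 p53 targets 3 fell and 0 rose, the cell cycle inhibitor CDKN1A (-0.81 ± 0.10), BTG2 (-0.80 ± 0.11) and the death receptor TNFRSF10B (-0.62 ± 0.08), against 5 that fell and 1 that rose when adjusted over the list alone (adjusted p = 0.0119, adjusted p = 0.5 with an estimated correlation). Of 11 metallothioneins MT2A fell (-0.68 ± 0.11), and 8 fell when adjusted over the list alone (adjusted p = 1.07e-05, adjusted p = 0.354 with an estimated correlation). Of 26 genes of cholesterol and fatty acid synthesis 3 fell, SREBF2 (-0.78 ± 0.09), SC5D (-0.59 ± 0.09) and SCD (-0.51 ± 0.09), against 6 that fell and 1 that rose when adjusted over the list alone (adjusted p = 0.0249, adjusted p = 0.638 with an estimated correlation).

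Stress and immune lists moved in part when turned. Of 15 heat shock proteins HSP90AA1 (0.64 ± 0.10) and HSPE1 (0.59 ± 0.09) rose and HSPB1 fell (-0.90 ± 0.10), with 4 and 1 when adjusted over the list alone (adjusted p = 0.00103, adjusted p = 0.375 with an estimated correlation). Of 33 interferon-stimulated genes MX1 (1.02 ± 0.13) and IFI44 (0.64 ± 0.09) rose and SAMD9 fell (-0.57 ± 0.09), with 6 and 2 when adjusted over the list alone (adjusted p = 0.00281, adjusted p = 0.354 with an estimated correlation). Lists that did not pass were the ATF4 and unfolded protein response (3 rose and 2 fell, with ASNS at 0.77 ± 0.11 and DDIT4 at -1.06 ± 0.13, adjusted p = 0.162), epithelial-mesenchymal transition (SNAI2 at -0.51 ± 0.09 and SPARC at -0.48 ± 0.09 fell, adjusted p = 0.0756), NF-kB and inflammatory cytokines (CXCL1 fell, -0.66 ± 0.10, adjusted p = 0.841) and hypoxia and glycolysis (0 of 20, adjusted p = 0.597). Among 8 targets of the aryl hydrocarbon receptor NQO1 and UGT1A6 rose, but the list median was -0.15 and its mean 0.05 (adjusted p = 0.977). No marker passed among fibroblast (8 measured), leukocyte (9), melanocyte (7) and endothelial genes (6), nor among 12 genes of the RNA interference machinery, and none of these lists passed (adjusted p = 0.405 to 0.979 with either correlation). For the NF-kB, fibroblast, melanocyte and RNA interference lists the median, the mean and the test also differed in sign.

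The arrays fell into 2 slide runs, which the labels do not name and which were inferred from a gap in the slide barcodes. Of these, 1 held 3 KEAP1 arrays and 1 held 3 scrambled arrays. The turned differences correlated weakly between the 2 runs, at r = 0.281 over all genes, of which 57.6% had the same sign in both. Of the 471 genes furthest from 0 in the slide run with 3 KEAP1 arrays, 298 had the same sign in the other, and 308 of 471 the other way round. KEAP1 was at -1.31 and -1.35 in the 2 runs and AKR1C1 at 2.39 and 2.17. With the slide run as a term in a fit of the 8 single arrays 1007 genes passed, but that fit estimated a correlation of -0.126 within replicates, so dye-swapped arrays of 1 replicate counted as at least independent. With the replicate number as a block 424 genes and 16 lists passed. The count of 471 fell to 4 without scrambled replicate 1, 25 without scrambled replicate 2, 39 without KEAP1 array 2 and 0 with the processed log ratios of Feature Extraction, where 3901 genes had an unadjusted p under 0.05. KEAP1 array 2 was the only array of scan day 2 and the only KEAP1 array in its slide run. It had 227 saturated Cy5 spots, against 82 to 141 on the other arrays. Whether these traits bear on the count without it was not tested. With the replicate labelled KEAP1 2 turned in place of the replicate labelled 1, 2029 genes passed, 905 higher and 1124 lower. KEAP1 was then at 1.42, AKR1C1 at -3.72, GCLM at -0.94, MMP1 at -1.02 and TMEM109 at 1.17.

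Scrambled siRNA against the mock reference asks what transfecting an siRNA without a target does beside the reagent alone. These ratios do not depend on the KEAP1 arrays, which enter only through the shared spread. As labelled, 0 genes passed in limma, 2842 had an unadjusted p under 0.05 and the lowest adjusted p was 0.112. With the replicate labelled KEAP1 1 turned the spread shrank and 1509 genes passed, 880 higher and 629 lower, against 728 with median centring, 532 higher and 196 lower. The largest increases were MMP1 (2.15 ± 0.09, adjusted p = 0.00183), MMP12 (1.55 ± 0.09), AKR1B10 (1.26 ± 0.08), PLAT (1.17 ± 0.08) and KRT1 (1.16 ± 0.13). The largest decreases were TMEM109 (-1.24 ± 0.06, adjusted p = 0.0026), CNIH4 (-1.13 ± 0.06), SIVA1 (-1.03 ± 0.06), the activin antagonist FST (-1.02 ± 0.08) and EIF4G2 (-0.94 ± 0.06). KEAP1 mRNA was at -0.04 ± 0.07 (adjusted p = 0.802) and NFE2L2 rose by 0.42 ± 0.08 (adjusted p = 0.0316), while a dimmer probe of NFE2L2 gave -0.07.

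Of the 30 lists 7 passed camera as labelled and 11 when turned, in all cases without passing at an estimated correlation (adjusted p = 0.799 to 0.84 as labelled and 0.577 to 0.644 when turned). When turned, 6 of 14 basal keratinocyte genes rose, TP63 (0.84 ± 0.06), KRT15 (0.51 ± 0.06) and ITGA6 (0.47 ± 0.06) among them, and 10 when adjusted over the list alone (adjusted p = 1.95e-09). Of the aldo-keto reductases 3 of 10 rose, AKR1B10, AKR1C1 (0.70 ± 0.06) and AKR1C3 (0.60 ± 0.06), and 3 when adjusted over the list alone (adjusted p = 0.00708). Of the iron and heme genes 3 of 14 rose, FTH1 (0.59 ± 0.06), FTL (0.51 ± 0.06) and HMOX1 (0.35 ± 0.06), against 5 that rose and 1 that fell when adjusted over the list alone (adjusted p = 0.00333). Of the p53 targets 4 of 16 rose, among them CDKN1A (0.57 ± 0.07) and BTG2 (0.56 ± 0.08), and 5 when adjusted over the list alone (adjusted p = 0.00708). Of 24 cell cycle genes 4 fell, among them PCNA (-0.41 ± 0.07), and 15 when adjusted over the list alone (adjusted p = 0.000221).

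In the same comparison 6 of 26 genes of cholesterol and fatty acid synthesis rose, among them HMGCS1 (0.62 ± 0.09) and SCD (0.43 ± 0.06), against 10 that rose and 1 that fell when adjusted over the list alone (adjusted p = 0.00708). The other lists that passed were hypoxia and glycolysis (3 of 20 rose, 8 adjusted over the list alone, adjusted p = 0.000391), wound keratins and alarmins (2 of 13, 4 adjusted over the list alone, adjusted p = 0.00708), metallothioneins (2 rose and 1 fell of 11, 6 and 1 adjusted over the list alone, adjusted p = 0.00708), ABC drug efflux transporters (2 of 9, 4 adjusted over the list alone, adjusted p = 0.0401) and epithelial-mesenchymal transition (2 of 14, 4 adjusted over the list alone, adjusted p = 0.0401). Their adjusted p was 0.577 to 0.644 with an estimated correlation. The interferon-stimulated genes did not pass (1 rose and 3 fell of 33, adjusted p = 0.173), and their median of -0.04 was 0.01 by median centring. The thioredoxin list (median -0.04, mean 0.03, median 0.04 by median centring) and the glutathione list (median 0.00, mean -0.03) did not pass either. Of the 160 measured members of the NRF2-related lists 19 rose and 3 fell. Without scrambled replicate 1 only 1 gene passed, without scrambled replicate 2 only 3, without KEAP1 array 2 only 61, and without the replicate labelled KEAP1 1 2162. With the processed log ratios of Feature Extraction 0 passed in limma (4136 at an unadjusted p under 0.05).

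KEAP1 siRNA against the mock reference gives a second control for the KEAP1 siRNA. As labelled, 0 genes passed in limma, 695 had an unadjusted p under 0.05 and the lowest adjusted p was 1.00. When turned, 537 genes passed, 240 higher and 297 lower. The largest increases were AKR1C1 (3.02, adjusted p = 1.17e-05), AKR1C3 (2.98, adjusted p = 1.17e-05), AKR1B10 (2.89, adjusted p = 5.22e-05), HMOX1 (1.55) and FTL (1.47). The largest decreases were KEAP1 (-1.38 ± 0.07, on whose direction the turn was chosen), PLEKHA1 (-1.23), MMP1 (-1.14), the kinase MAPK6 (-1.09) and FST (-1.05). FST was as low in scrambled siRNA, at -1.02, and did not pass between the siRNAs (-0.03 ± 0.11, adjusted p = 0.923). Relative to mock, SRXN1 (1.32), GCLC (1.14), TKT (1.02), PGD (1.01), GCLM (0.99), NQO1 (0.94), SLC7A11 (0.94), MAFG (0.86), ABCC3 (0.81) and TXNRD1 (0.75) also rose, and KRT17 (-0.74), KRT15 (-0.68) and TP63 (-0.43) fell. NFE2L2 was at 0.05 (adjusted p = 0.759).

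Tested on this comparison after seeing the data, none of the 30 lists passed camera as labelled (lowest adjusted p = 0.894). When turned 17 passed camera and 12 fry's directional test, and none passed camera with an estimated correlation (adjusted p = 0.294 to 0.398 for the 17). Aldo-keto reductases (4 of 10 rose), iron and heme genes (4 of 14), pentose phosphate and NADPH genes (6 of 13), glutathione genes (5 of 18), the thioredoxin system (4 of 19) and quinone and drug metabolism (9 rose and 1 fell of 23) were higher. Adjusted over the list alone, 5, 6, 6, 5, 4 and 11 of their members rose, and 1, 0, 1, 0, 1 and 2 fell. Basal keratinocyte genes (5 of 14 fell), wound keratins (4 of 13) and differentiating keratinocyte genes (2 of 21) were lower, with medians of -0.29, -0.31 and -0.13. Adjusted over the list alone, 10, 5 and 7 of their members fell, and 1, 0 and 1 rose. The other lists that passed upward were ABC transporters (3 rose), other NRF2-responsive genes (5), heat shock proteins (3), hypoxia and glycolysis (2), proteasome subunits (1), interferon-stimulated genes (1 rose and 1 fell) and cell cycle genes (none), and metallothioneins passed downward (none). By median centring the glutathione and interferon medians of 0.08 and 0.03 became -0.03 and -0.03. With the replicate labelled KEAP1 2 turned in place of the replicate labelled 1, the same number of genes, 537, passed with every sign reversed, 297 higher and 240 lower. Leaving out KEAP1 array 2 left 126 genes, the processed log ratios of Feature Extraction left 0 in limma (4181 at an unadjusted p under 0.05), and leaving out a replicate left 201 to 362.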

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

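The tests of the mirrored KEAP1 replicate, of the NRF2-related genes raised by scrambled siRNA, and those that chose genes on 1 dye orientation or 1 replicate were chosen only after the results were seen. The other tests of the genes further from mock in the scrambled group and the splits of the replicates were set before their results were seen, but on turned values, a choice made after seeing the data, except for the split as labelled.

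The ratios of the replicate labelled KEAP1 1 mirrored those of the replicate labelled KEAP1 2: all 15 genes beyond 1 log2 unit in both had opposite signs, and over all genes the replicates correlated at r = -0.463. Scanner channels exchanged at reading are argued against by 222 control spots that carry only Cy3, whose median log2 Cy5 over Cy3 stayed below 0 on both arrays of that replicate (-7.90 the higher of the 2), as on all other arrays (-3.79 to -9.80). A culture in which the siRNA lowered its target while the other genes moved the other way is argued against by KEAP1 itself, at 1.43 above mock in that replicate as labelled. Dyes, or sample and reference, exchanged for both arrays of the pair remain a candidate explanation, because across 200 genes chosen from the scrambled arrays alone the replicate labelled 1 correlated at r = -0.362 with the scrambled mean and the replicate labelled 2 at r = 0.297. Ratios over 1 shared mock RNA tend to correlate above 0 even without a shared effect of transfection, so these values bear on the sign of a replicate and not on a response, and a turn of the replicate labelled 2 would leave KEAP1 mRNA raised by its own siRNA in both replicates.

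Some NRF2-related genes were raised by scrambled siRNA too when turned (0 genes passed in limma as labelled, 2842 at an unadjusted p under 0.05): of the 160 measured members of these lists 19 rose against mock and 3 fell, no list passed with an estimated correlation, and 7 of the 19 rose further with KEAP1 siRNA (AKR1B10, AKR1C1, AKR1C3, FTL, HMOX1, MAFG and TKT). RNA of KEAP1 siRNA cells in the scrambled samples is argued against as the only cause for all 7. TKT would need a share of at least 39.3% and AKR1C3 no more than 7.91%, which lie 31.4 percentage points apart. AKR1C1 (8.83% and 8.76%) and AKR1C3 (7.91% and 7.12%) would need nearly the same share in the scrambled replicates. For these genes alone it stays open. A dye bias equal on all arrays is argued against by the design alone, since it cancels in the mean of swapped arrays, and the lowest ratio on a scrambled array, 0.10, adds little because members were chosen over both orientations. A dye bias that differs between arrays, which would leave about as many above as below mock, stays open for part of them. Of members chosen on 1 replicate, with its dyes swapped, 9 of 11 (81.8%) and 11 of 11 were above mock on the other. Of those chosen on 1 orientation 9 of 11 (81.8%) and 7 of 9 (77.8%) were above mock on the other. These last shares cannot separate the kinds of dye bias, because an equal bias stays in such members and changes sign on the other orientation. A response to the transfected siRNA, which the design gives as the difference between scrambled and mock, stays open as a hypothesis, as do a departure of the mock RNA, which stands as 1 RNA, and an off-target effect of the scrambled sequence, which was not tested.

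Of the 471 genes that passed between the siRNAs when turned, 286 had the scrambled ratio further from 0 than the KEAP1 ratio. A dye bias equal on all arrays is argued against by the design alone, as above, and the 276 (96.5%) with the same sign on all 4 scrambled arrays add little because the choice over dye-balanced means favours 1 sign. A dye bias that differs between arrays stays open for part of them. Of genes chosen on 1 replicate, with its dyes swapped, 208 of 248 (83.9%) and 197 of 220 (89.5%) kept the scrambled sign on the other. Of genes chosen on 1 dye orientation 204 of 311 (65.6%) and 234 of 275 (85.1%) kept it on the other. These last shares cannot separate the kinds of dye bias, because an equal bias stays in such genes and changes sign on the other orientation. Over all genes, ratios to mock of scrambled arrays with the same dyes correlated at r = 0.704 and 0.616. Those of swapped arrays of 1 replicate correlated at -0.245 and -0.066. The loess normalization as the cause for these genes, which were chosen under it, is argued against by the 273 (95.5%) that kept sign and order with arrays centred on the median. How many genes passed each way did depend on it, with 69 higher and 379 lower by median centring against 174 and 297. A response to the scrambled siRNA and a departure of the mock RNA cannot be separated here, because every ratio has the mock RNA below the line, and both stay open.

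The 4 biological replicates can be split in only 3 ways into groups of 2, too few for a share under 0.05. As labelled, the real split gave 0 genes by limma (1911 at an unadjusted p under 0.05), the highest of the others also 0, so 3 of the 3 splits gave as many. When turned, the real split gave 471 genes and the highest of the others 0, so 1 of the 3 gave as many. The turn had made the 2 KEAP1 replicates alike before the splits were compared, which favours the real split. The turned count is therefore no support for the grouping.

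The median Cy5 background of KEAP1 array 4 was 61, while the other 3 KEAP1 arrays were at 62, which set it apart from its group. It was the only such value among 24 groups of array measures tested, and chance sets apart about 1 in 20.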

How the results depend on the processing

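Turning either KEAP1 replicate, leaving out KEAP1 array 2 or 3, crossing the replicate numbers, testing the lists on KEAP1 siRNA against mock, running the lists with the slide run as a block and every alternative of a turned fit were chosen after seeing the data. The other alternatives were planned. Counts are of genes past an adjusted p of 0.05 in limma unless stated, and where the table shows no reason for a change, the cause was not tested.

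KEAP1 siRNA against scrambled siRNA as labelled gave 0 genes (1911 at an unadjusted p under 0.05) and kept 0 with other background, normalization, filter, probe, variance, threshold, 1-dye, slide run and array settings. It gave 55 genes with all 8 arrays and a random block, 471 with the replicate labelled KEAP1 1 turned, 2029 with the replicate labelled 2 turned, and 0 to 1889 when a biological replicate was left out. The KEAP1 value itself, 0.10 as labelled, reversed to -1.34 when turned (adjusted p = 0.00661), to -0.13 with median centring (adjusted p = 0.970, near 0 in both) and to -1.29 without the replicate labelled KEAP1 1 (adjusted p = 0.00895). It rose to 1.48 without the replicate labelled KEAP1 2 (adjusted p = 0.00417). With the replicate number as a block the counts were 0 genes as labelled (2279 at an unadjusted p under 0.05) and 424 when turned. The deviations of same-numbered replicates correlated at 0.136 as labelled and -0.102 when turned, and crossing the numbers gave 347 genes when turned.

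The turned comparison, 471 genes (174 higher and 297 lower), kept within 1.5 times with scaling between arrays (347), the mean of a gene's probes (335), no filter (333), another variance model (431), a fold of at least 1.5 (351) and median centring (448, but 69 higher and 379 lower). It gave 1609 with a random block, 0 with Agilent's processed log ratios (3901 at an unadjusted p under 0.05), 39 without KEAP1 array 2, 193 without KEAP1 array 3, 1085 at an adjusted p under 0.10, 1599 without background correction, 9 on the Cy3 arrays alone, 4 on the Cy5 arrays alone, 1007 with the slide run as a block in a fit of the single arrays, 1994 with the stricter filter, and 4 to 346 when a biological replicate was left out. The fits of the single arrays, with the random block or the slide run, estimated correlations of 0.0055 and -0.126 within replicates when turned, so dye-swapped arrays counted nearly as, or beyond, independent replicates. With 1 replicate left in a group, that replicate is assumed to vary like those of the other group. Of the 471 genes 269 also passed without the replicate labelled KEAP1 1, all in the same direction, where chance would share 6.20 if the 2 fits were independent, which they are not.

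KEAP1 siRNA against mock gave 0 genes as labelled (695 at an unadjusted p under 0.05), 537 with either KEAP1 replicate turned, and 0 to 362 when a replicate was left out. When turned, the 537 became 2180 with a random block, 0 with Agilent's log ratios (4181 at an unadjusted p under 0.05), 126 without array 2, 340 without array 3, 2303 without background correction, 1949 with the slide run block, 2588 with the stricter filter, and 201 to 362 when a replicate was left out.

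Scrambled siRNA against mock gave 0 genes as labelled (2842 at an unadjusted p under 0.05), 617 with a random block, 1509 with either KEAP1 replicate turned, 23 on the Cy3 arrays, 201 with the slide run block, and 0 to 2162 when a replicate was left out. When turned, the 1509 became 3097 with a random block, 0 with Agilent's log ratios (4136 at an unadjusted p under 0.05), 61 without array 2, 626 without array 3, 728 with median centring (532 higher and 196 lower), 3012 without background correction, 3370 on the Cy5 arrays, 928 with scaling, 2698 with the slide run block, 3659 with the stricter filter, and 1 to 2162 when a replicate was left out.

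Lists past camera between the siRNAs as labelled were 5 of 30, and became 1 with Agilent's log ratios, 3 without array 3, 16 and 11 with replicate 1 or 2 turned, 0 with an estimated correlation, 1 and 0 with fry's directional and mixed tests, and 2 to 15 when a replicate was left out. When turned they were 16, and became 0 with an estimated correlation, 8 and 26 with fry, and 10 with median centring. With the replicate block they were 5 as labelled and 16 when turned. For KEAP1 siRNA against mock when turned they were 17, and became 0 with an estimated correlation and 28 with fry's mixed test. For scrambled siRNA against mock as labelled they were 7, and became 3 with Agilent's log ratios, 11 with either replicate turned, 0 with an estimated correlation, 0 and 2 with fry, and 5 to 13 when a replicate was left out. When turned they were 11, and became 4 with Agilent's log ratios, 0 with an estimated correlation, and 2 and 26 with fry.

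Of the 81 named genes past the threshold when turned, 0 reversed under the alternatives of that fit, of which the stricter filter kept only 78 of them, while 81 lost the threshold with Agilent's log ratios, 78 on the Cy5 arrays, 74 on the Cy3 arrays, 78 without scrambled replicate 1, 66 without scrambled replicate 2, 56 without array 2 and 27 without array 3. The absence of reversals says little. The random block, the replicate blocks, the other variance model and the filters left each difference unchanged, so no sign could reverse there. The largest changes were also chosen with replicates that did not overlap, so leaving out a replicate could not reverse them. The values of the 81 genes stayed about as large. Their median ratio to the reported value was 1.06 with Agilent's log ratios, 0.96 on the Cy5 arrays and 1.04 on the Cy3 arrays. Of all 145 named genes, which did not pass the threshold as labelled, 27 changed sign with the replicate labelled KEAP1 1 turned, 53 with the replicate labelled 2 turned, 24 without KEAP1 replicate 1 and 46 without KEAP1 replicate 2. Agilent's log ratios moved the median of all genes to -0.11 between the siRNAs when turned, against -0.01. Signal over background limits dim genes: Cy3 was well above background at 60.5% of the spots on the array with the lowest share.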

Other observations

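All of the values here were chosen after they were seen, and no new test was run on them.

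Several genes named above had probes at different positions that gave different values when turned. The brightest TP63 probe (hg17 chromosome 3, 191097665 to 191097724) gave -1.27 between the siRNAs, and the dimmer one (191069135 to 191069194) gave -0.25. TMEM109 was at 1.31 with its brighter probe (hg17 chromosome 11, 60447430 to 60447489) and at 0.22 with the other (60443882 to 60443941). Of 8 SUMO2 probes, SUMO2 being a small protein modifier, 7 lay between 0.14 and 0.77 and 1 was at -0.24. For the death receptor TNFRSF10B, a p53 target, the brighter probe was at -0.62 and the dimmer one at 0.16. NFE2L2 was at -0.37 and 0.01 with its 2 probes, and the cell cycle inhibitor CDKN1A at -0.81 and -0.30. RXRA was at -0.58 with its brighter probe and at -0.04 with the other.

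KEAP1 array 3 was the brightest in Cy5, with a median signal of 703, and had the most spots with an outlier flag, 288, against 67 to 112 on the other arrays. Its control spots that carry only Cy3 had a median log2 Cy5 over Cy3 of -3.79, against -7.90 to -9.80 on the other arrays. FST, an antagonist of activin, was lower than mock in both groups when turned (-1.05 in KEAP1 siRNA and -1.02 in scrambled siRNA), and INHBA, which encodes an activin subunit, was at 0.13 and 0.92.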
